A study of Mus musculus with 12 samples.

How the data were processed

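Total RNA of hepatocytes from 12-week-old wild-type female mice was sequenced from NEBNext Ultra libraries, a kit that does not mark strand, per the labels' protocols. Reads of overlapping genes on opposite strands therefore cannot be told apart. The labels name 12 libraries in 4 groups of 3: pericentral and periportal hepatocytes of fed mice, and pericentral and periportal hepatocytes of mice fasted for 24 h. Pericentral hepatocytes (PC) lie next to the central vein of the liver lobule and periportal hepatocytes (PP) next to the portal tract. The labels name digitonin, a detergent used to destroy the hepatocytes of one zone so that those of the other can be isolated. The labels call the libraries of a group biological replicates, and do not say whether a PC and a PP library of one number came from one mouse. Proteins and male mice, which the title of the series also concerns, were not analysed here.

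The deposited table holds estimated counts per gene, which need not be whole numbers. The submitters' processing notes name kallisto 0.46.0, which assigns reads to transcripts without full alignment, and the build mm10. How transcripts were summed to genes, the transcript annotation, trimming and strand settings were not given in the sources used here. Estimated counts divide reads shared by near-identical genes by a model, so the values of close paralogs such as the Cyp2c, Cyp3a, Gsta, Mt1 and Mt2 families are uncertain. The table lists 28030 Ensembl gene identifiers, of which 27645 were found in the GENCODE M21 annotation of GRCm38, which gave coordinates and symbols. 385 identifiers had no symbol. Xist was not among the listed identifiers. Between 28.0% and 32.8% of the values of a library were not whole numbers. All values were rounded to whole numbers before any test, which moved the total of a library by at most 85.8 counts.

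Total estimated counts per library ranged from 16245846 to 27449412. Fed PC libraries held 19081355 to 27449412, fed PP libraries 18880742 to 23264225, fasted PC libraries 16245846 to 19564921 and fasted PP libraries 21820654 to 23969208. Genes of low CPM rest on few counts and carry wide errors. Libraries of one group were compared by a chi-square test over genes. Chi-square values per degree of freedom ran from 25.8 to 86.6, so no pair agreed within sampling noise as 1 library deposited 2 times would. Separate mice spread more than sampling noise in any case, and that the libraries are replicates rests on their labels alone.

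Genes were kept by edgeR's filterByExpr, which left 12086, and libraries were scaled by trimmed means of M values (TMM). One model with a mean for each of the 4 groups was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust), with 8 residual degrees of freedom and a common biological coefficient of variation of 0.2055. The contrasts were PC against PP in fed mice, PC against PP in fasted mice, fasted against fed in PC, fasted against fed in PP, and the difference between the last pair (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the unshrunk log2 fold change divided by the square root of the test statistic. Levels are in CPM, the usual count per unit of library size, with TMM-scaled library sizes, as mean ± SD with n = 3 libraries per group. With 8 residual degrees of freedom, p-values measure the spread between these libraries.

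Gene lists, 29 in number, were fixed with the rule for named genes before the data were examined. They share some genes and cover zone markers, liver metabolism, stress and clock genes, ribosomal and mitochondrial genes, and markers of other liver cells. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The named genes are the 5 with the highest and the 5 with the lowest log2 fold change per comparison of 2 groups among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted models and pseudogenes; fixed anchor genes of zonation and of fasting; up to 2 called members per direction of each list; and Y-linked genes as a sex check. For the interaction no gene met the rule.

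The fits were tested on simulated data with the means, dispersions and library sizes of the real libraries. Of genes changed 2-fold, 62.7% were recovered for the zone contrast in fed mice (11866 genes in that step), 49.2% for the zone in fasted mice (11886 genes), 53.0% for fasting in PC (11864 genes), 54.5% for fasting in PP (11878 genes) and 31.3% for the interaction (11862 genes). Of genes changed 4-fold, 84.8%, 80.0%, 78.8%, 86.2% and 60.9% were recovered in the same order, and of genes changed 1.5-fold, 23.9%, 9.1%, 23.4%, 16.4% and 1.5%. For the zone in fed mice (11865 genes), camera called the 1 raised list of 20 genes at 1.5-fold and 0 of 28 unchanged lists. No correlation between genes is among the simulated properties, so 0 of 28 does not cover correlated lists. Unchanged genes made up 12 of 126, 4 of 93, 5 of 107, 2 of 105 and 2 of 63 calls in the order above. The first is above the 0.05 allowed on average.

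Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a mean CPM of at least 1, a fit to only the groups compared, the replicate number as a block, removal of the 20 most abundant genes, and leaving out each library in turn. For the gene lists, leaving out libraries was added after seeing the data. Counts of 2 or more list members are given again where 1 left-out library moved them by over 1.5 times, and counts of 0 or 1 where it changed them.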

Results

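The series asks how messenger RNA differs between the zones of the liver lobule and between feeding and fasting in mouse hepatocytes. Its 12 libraries form 4 groups of 3: PC and PP hepatocytes of fed mice, and PC and PP hepatocytes of fasted mice. Mice were trained for 3 days with 16 h of fasting and 8 h of feeding. Fed mice were killed after 4 h of feeding with 20% sucrose in the drinking water, and fasted mice after 24 h without food or sucrose, at the same time of day. Libraries held 16245846 to 27449412 estimated counts, and 12086 genes were tested. Ddx3y, Eif2s3y, Uty and Kdm5d, which lie on the Y chromosome, were at or below 0.58 CPM in every library, and all libraries are labelled female.

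The libraries separated by feeding and by zone. The first principal component of log2 CPM held 30.2% of the variance and the second 26.1%. Albumin (Alb) took 6.7% to 8.48% of the counts of PC libraries and 10.63% to 13.24% of those of PP libraries. One library stood apart within its group: in fasted PC replicate 1, the pericentral gene Glul stood at 172.0 CPM, against 3639 and 2353 CPM in the other fasted PC libraries.

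**Figure D1:**
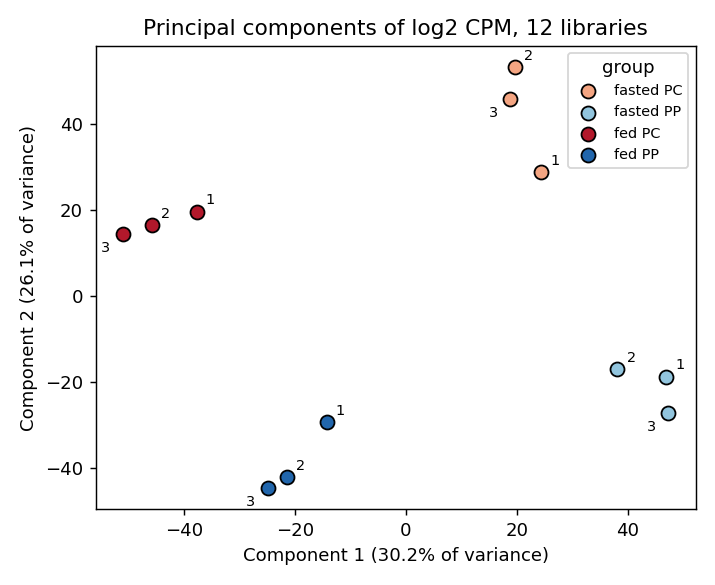
Principal components of log2 CPM over the 12 libraries, with component 1 on the x axis (30.2% of the variance) and component 2 on the y axis (26.1%), in units of component scores. Points are libraries, coloured by group and marked with the replicate number, and the 4 groups lie apart, with fasted PC replicate 1 at 28.8 on component 2 and replicates 2 and 3 at 53.3 and 45.95.

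In fed mice, PC and PP hepatocytes differed in many genes that mark the zones. Oat, ornithine aminotransferase, stood at 1705 ± 81.9 CPM (SD, n = 3) in PC against 24.3 ± 9.78 in PP, a log2 fold change of 6.13 ± 0.65 (SE; edgeR adjusted p = 0.00074). Cyp1a2, a cytochrome P450 of drug metabolism, was higher by 3.72 ± 0.42 on the log2 scale (edgeR adjusted p = 0.00073). In the opposite direction, Cyp2f2, a cytochrome P450, stood at 95.2 ± 23.6 CPM in PC against 1966 ± 280 in PP, a log2 fold change of -4.37 ± 0.48 (edgeR adjusted p = 0.00073). Sds, serine dehydratase, fell by 4.85 on the log2 scale from PP to PC, with 217.9 ± 58.6 CPM in PP.

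The 5 genes that were highest in fed PC by log2 fold change were Slc13a3, a dicarboxylate transporter (7.13 ± 0.96), Slc1a2, a glutamate transporter (6.58 ± 1.197), Oat, Lhpp (5.75 ± 0.70) and Tnfrsf19 (5.07 ± 0.54). The 5 lowest were Aldh1b1, a mitochondrial aldehyde dehydrogenase (-5.90 ± 0.74), Cryl1 (-5.54 ± 0.41), Mmd2 (-5.30 ± 0.30), Eci3 (-5.21 ± 0.67) and Sds. By the rule that chose these 10 genes, the 3 libraries of one zone all lay above the 3 of the other in each. On GRCm38 (mm10), Slc13a3 spans chromosome 2 from 165405028 to 165473230, Oat chromosome 7 from 132557478 to 132576398, Aldh1b1 chromosome 4 from 45799022 to 45804604 and Sds chromosome 5 from 120476526 to 120483932. The call of Slc1a2 ended without fed PP replicate 1 (edgeR adjusted p = 0.063) and without fed PP replicate 2 (0.073).

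Of 24 tested pericentral markers, 20 were higher in fed PC and 0 lower (23 adjusted over the list alone), with a median log2 fold change of 3.19 (camera adjusted p = 1.6e-56, and adjusted p = 0.012 with an estimated correlation). Lgr5, a Wnt pathway receptor, was higher by 4.28 ± 0.50, and Rgn, regucalcin, by 2.07 ± 0.24. Axin2, a Wnt target, was higher by 3.10 ± 0.50 (edgeR adjusted p = 0.0045). Cyp2e1, a cytochrome P450 that oxidises ethanol, was higher by 3.76 ± 0.67 (edgeR adjusted p = 0.011), a call that ended without fed PP replicate 2 (0.051). Glul, glutamine synthetase, stood at 1834 ± 414 CPM in PC against 140.1 ± 36.2 in PP, yet its adjusted p was 0.052 in edgeR. Without fasted PC replicate 1, which enters the shared spread, that p was 0.00068.

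Of 24 periportal markers, 16 were lower in fed PC and 0 higher (23 adjusted over the list alone), with a median of -1.91 (camera adjusted p = 9.6e-41, and adjusted p = 0.013 with an estimated correlation). Cdh1, the adhesion protein E-cadherin, had a log2 fold change of -3.79 ± 0.30, and Etnppl, ethanolamine-phosphate phospho-lyase, one of -3.61 ± 0.38. Hal, histidine ammonia-lyase, had a log2 fold change of -2.81 ± 0.68 with an edgeR adjusted p of 0.050, and Gls2, liver glutaminase, one of -2.18 ± 0.54 (0.053). Neither was called, and each was called when any 1 fasted PC library was left out (-2.79 and -2.17 without fasted PC replicate 1). Pck1, which makes phosphoenolpyruvate for gluconeogenesis, had -2.64 ± 0.65 (edgeR adjusted p = 0.051), and Ass1, a urea cycle enzyme, -0.63 ± 0.24 (0.185). For Pck1, zone in fed mice, leaving out fed PC replicate 1 gave a call at -3.67 and leaving out fed PP replicate 3 a call at -3.00. The 16 periportal markers lower in PC became 10 without fed PC replicate 3.

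Lists of metabolism and the acute phase also had calls between the zones of fed mice. Some members, such as Fbp1 and Arg1, are zone markers too. Of 27 xenobiotic metabolism genes, 10 were higher and 2 lower in PC (13 and 2 adjusted over the list alone), with Cyp2c38, which has close paralogs and is uncertain, higher by 2.77 ± 0.34 (camera adjusted p = 2.0e-08, and adjusted p = 0.105 with an estimated correlation). Of 12 gluconeogenesis genes, 4 were lower in PC and 0 higher (6 adjusted over the list alone), among them Fbp1, fructose-bisphosphatase, at -0.67 ± 0.11 (camera adjusted p = 3.3e-06, and adjusted p = 0.012 with an estimated correlation). Of 14 genes of bile acid synthesis and transport, 3 were higher and 0 lower in PC (5 and 2 adjusted over the list alone), with Hsd3b7 at 1.26 ± 0.18 and Cyp27a1, a sterol hydroxylase, at 1.07 ± 0.18 (camera adjusted p = 0.00016, and adjusted p = 0.188 with an estimated correlation). Of 16 acute phase genes, 3 were lower in PC (9 adjusted over the list alone), with Hpx, the haem carrier hemopexin, at -1.43 ± 0.15 (camera adjusted p = 1.1e-06, and adjusted p = 0.051 with an estimated correlation). The 10 xenobiotic metabolism genes higher in PC became 6 without fed PP replicate 2, and the 2 lower in PC became 0 without fed PC replicate 1, 2 or 3 or fed PP replicate 1, 2 or 3 and 1 without fasted PP replicate 2 or 3. The 3 genes of bile acid synthesis and transport higher in PC became 5 without fed PP replicate 1. The 3 acute phase genes lower in PC became 5 without fasted PC replicate 1. Of 27 genes of amino acid catabolism, 3 were higher and 5 lower in fed PC (8 and 9 adjusted over the list alone), and camera did not call the list (adjusted p = 0.427) but called it without fasted PC replicate 1 (0.0017). The 5 amino acid catabolism genes lower in PC became 8 without fasted PC replicate 1 or 2. In fed PC, 1 of 13 genes of glycolysis and fructolysis was lower (3 adjusted over the list alone; camera adjusted p = 0.065), 1 of 8 urea cycle genes was lower (2 adjusted over the list alone; camera adjusted p = 0.0997), and 1 of 16 autophagy genes was higher (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.582). Camera called the glycolysis list without fed PC replicate 3 (adjusted p = 0.0030) or fed PP replicate 1 (0.0085), and the urea cycle list without fed PP replicate 2 (0.0497). Glycolysis and fructolysis genes lower in PC went from 1 to 0 without fed PC replicate 1 or 2, fed PP replicate 2 or 3, fasted PC replicate 2 or 3 or fasted PP replicate 1, 2 or 3. Urea cycle genes lower in PC went from 1 to 0 without fed PC replicate 1, 2 or 3 or fed PP replicate 2 or 3 and 2 without fasted PC replicate 1. Autophagy genes higher in PC went from 1 to 0 without fed PC replicate 1 or 3 or fed PP replicate 2, and those lower in PC from 0 to 1 without fed PC replicate 1 or 3 or fed PP replicate 1.

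Camera also called lists of which few or no members passed edgeR in fed mice. Of 25 cholesterol synthesis genes, 1 was higher in PC (1 adjusted over the list alone; camera adjusted p = 2.1e-05, and adjusted p = 0.656 with an estimated correlation). Of 74 nuclear genes of oxidative phosphorylation, 3 were lower (3 adjusted over the list alone), and of 13 mitochondrially encoded genes 1 was lower (1 adjusted over the list alone), with camera adjusted p = 8.9e-06 and 0.0054. No member of the lists of fatty acid oxidation and ketogenesis (19 genes, median 0.17), PPARalpha targets (20, median 0.26) and unfolded protein response (18, median -0.41) was called, with 0 adjusted over the list alone, at camera adjusted p = 0.0069, 0.031 and 0.020. For these 5 lists too the adjusted p = 0.656 with an estimated correlation. Leaving out 1 library ended the camera call of fatty acid oxidation and ketogenesis (adjusted p = 0.073 without fed PC replicate 1 and 0.257 without fed PP replicate 3), PPARalpha targets (0.175 without fed PC replicate 1, 0.257 without fed PP replicate 3 and 0.058 without fasted PP replicate 3) and the unfolded protein response (0.195 without fed PC replicate 3 and 0.435 without fed PP replicate 1). The 3 nuclear genes of oxidative phosphorylation lower in PC became 0 without fed PC replicate 1 or 2 or fed PP replicate 2 and 1 without fed PC replicate 3 or fed PP replicate 1. Cholesterol synthesis genes higher in PC went from 1 to 0 without fed PC replicate 2 or 3 or fed PP replicate 1 or 2 and 4 without fasted PP replicate 3. Mitochondrially encoded genes lower in PC went from 1 to 0 without fed PC replicate 1, 2 or 3 or fed PP replicate 1 or 3. Genes of fatty acid oxidation and ketogenesis higher in PC went from 0 to 4, and PPARalpha targets from 0 to 3, without fed PP replicate 1. Genes of the unfolded protein response lower in PC went from 0 to 1 without fed PC replicate 1. Camera did not call cytosolic ribosomal proteins in fed mice (adjusted p = 0.130, with 0 of 81 genes called and 0 adjusted over the list alone), but called them without fed PP replicate 3 (2.1e-05).

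edgeR called 570 genes between the zones of fed mice, 271 higher and 299 lower in PC. Leaving out 1 library gave 374 without fed PC replicate 1, 292 without fed PC replicate 2, 338 without fed PC replicate 3 and 309 without fed PP replicate 2. 566 of the called genes showed no overlap between the groups, as did 26.0% of all tested genes, where chance gives 10%. The larger side turned with no filter on low counts (276 higher and 243 lower), and without fed PC replicate 1 (190 and 184), fed PC replicate 2 (162 and 130), fed PC replicate 3 (173 and 165), fed PP replicate 3 (210 and 200), fasted PP replicate 1 (293 and 274), fasted PP replicate 2 (288 and 278) or fasted PP replicate 3 (322 and 291).

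**Figure D2:**
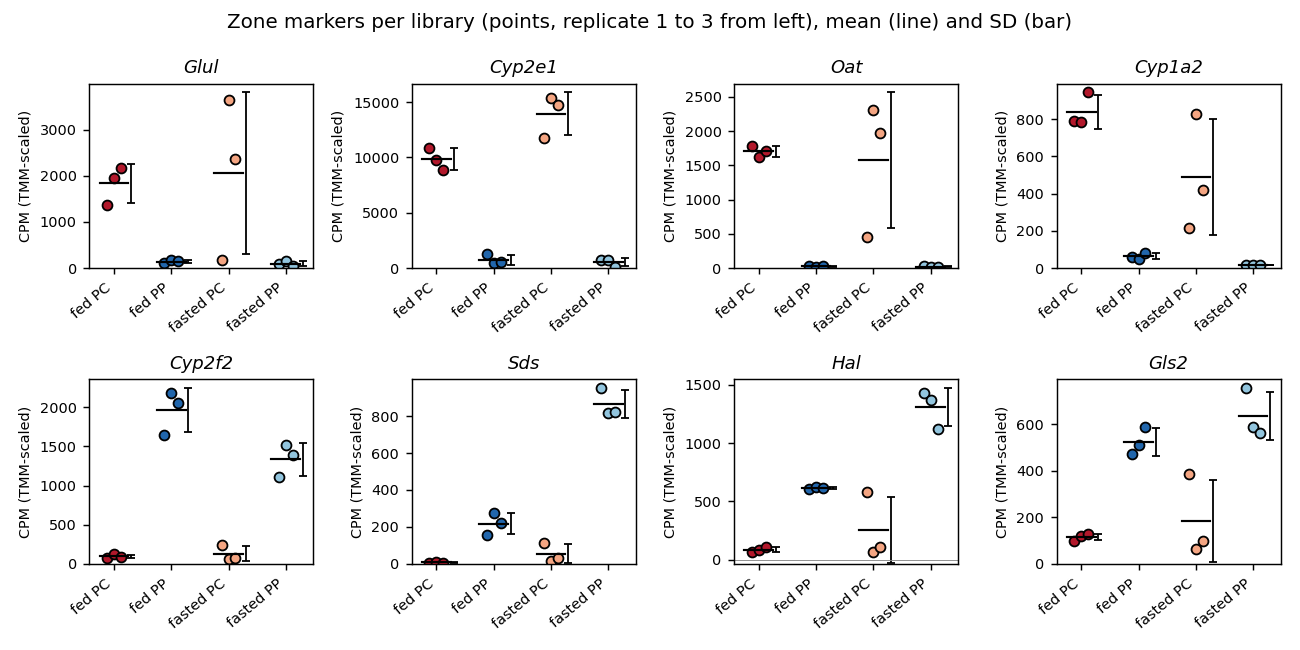
Levels of 8 zone markers in TMM-scaled CPM (y axis) in the 4 groups (x axis). Points are libraries, replicates 1 to 3 from left, lines are means and bars are SDs of n = 3. In fasted PC replicate 1, Glul stands at 172.0 CPM and Hal at 578.9 CPM, apart from the other fasted PC libraries.

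After 24 h of fasting, PC and PP hepatocytes differed in many of the genes that differed in fed mice. Cyp2e1 stood at 13970 ± 1917 CPM in fasted PC against 532.4 ± 357 in fasted PP, a log2 fold change of 4.71 ± 0.70 (edgeR adjusted p = 0.0036). Oat was higher by 6.42 ± 0.66 (edgeR adjusted p = 0.00074) and Cyp1a2 by 4.91 ± 0.44 (0.00029). Sds was lower in PC, at -4.01 ± 0.65 (edgeR adjusted p = 0.0061) and 864.6 ± 75.5 CPM in PP, and Cyp2f2 was lower at -3.38 ± 0.46 (0.0019).

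The 5 highest genes in fasted PC were Cyp3a41b (8.75 ± 2.21), Slc1a2 (8.71 ± 1.34), Slc13a3 (7.62 ± 1.06), Cyp3a16 (6.88 ± 1.72) and Lhpp (6.87 ± 0.74), and the 5 lowest were Aldh1b1 (-5.10 ± 0.72), Mmd2 (-4.67 ± 0.31), Cryl1 (-4.42 ± 0.39), Fgfr2, a fibroblast growth factor receptor (-4.31 ± 0.53), and Sds. Cyp3a41b and Cyp3a16 have near-identical copies and are uncertain. Cyp3a41b stood at 234.8 CPM in fasted PC replicate 1 and at 4.33 and 7.04 CPM in the other fasted PC libraries; without replicate 1 it had an edgeR adjusted p of 0.083. Cyp3a16 stood at 97.2 CPM in that library, and had an edgeR adjusted p of 0.072 without it. Both calls also ended when most of the other libraries were left out, with the highest adjusted p at 0.171 for Cyp3a41b without fasted PP replicate 2.

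Of 24 pericentral markers, 20 were higher in fasted PC and 0 lower (24 adjusted over the list alone), with a median log2 fold change of 4.06 (camera adjusted p = 1.1e-59, and adjusted p = 0.012 with an estimated correlation). Lgr5 was higher by 6.04 ± 0.58, Rgn by 2.54 ± 0.25 and Axin2 by 3.51 ± 0.53. Glul was higher by 4.46 ± 0.94 (edgeR adjusted p = 0.023), and this call ended without fasted PC replicate 2 (0.071), fasted PC replicate 3 (0.060), fasted PP replicate 1 (0.089) or fasted PP replicate 3 (0.091). Of 24 periportal markers, 17 were lower in PC and 0 higher (22 adjusted over the list alone), with a median of -1.84 (camera adjusted p = 1.1e-35, and adjusted p = 0.012 with an estimated correlation). Etnppl had -3.24 ± 0.37 and Cdh1 -2.91 ± 0.30. Hal had -2.37 ± 0.67 (edgeR adjusted p = 0.075), Gls2 -1.79 ± 0.54 (0.091), Ass1 -0.78 ± 0.24 (0.077) and Pck1 -0.88 ± 0.61 (0.50), and none of these 4 was called. Ass1 was called at -0.98 without fasted PP replicate 2 and at -0.78 without fed PP replicate 3. In fasted PC replicate 1, Hal stood at 578.9 CPM against 69.9 and 108.6 CPM, and Gls2 at 385.6 CPM against 65.4 and 99.7 CPM. Without this library, Hal had a log2 fold change of -3.88 and Gls2 one of -2.95, both called.

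Some genes of sugar and amino acid metabolism were also called between the zones of fasted mice. Of 13 genes of glycolysis and fructolysis, 5 were lower in PC and 0 higher (9 adjusted over the list alone), with Tkfc, which phosphorylates glyceraldehyde, at -1.33 ± 0.20 (camera adjusted p = 1.5e-06, and adjusted p = 0.165 with an estimated correlation). Of 12 gluconeogenesis genes, 6 were lower in PC (6 adjusted over the list alone), with Fbp1 at -0.80 ± 0.11 (camera adjusted p = 2.0e-07, and adjusted p = 0.012 with an estimated correlation). Of 27 genes of amino acid catabolism, 9 were lower and 2 higher in PC (11 and 4 adjusted over the list alone), with Gldc, of the glycine cleavage system, at -2.38 ± 0.37 and Sdsl at -3.39 ± 0.46 (camera adjusted p = 0.0018, and adjusted p = 0.281 with an estimated correlation). Of 8 urea cycle genes, 2 were lower (4 adjusted over the list alone), with Asl, argininosuccinate lyase, at -1.19 ± 0.24 (camera adjusted p = 0.014, and adjusted p = 0.477 with an estimated correlation). The urea cycle list was not called without fasted PC replicate 2 (camera adjusted p = 0.094) or fasted PP replicate 1 (0.099). The 5 glycolysis and fructolysis genes lower in PC became 3 without fed PC replicate 1 or 2, fed PP replicate 2, fasted PC replicate 1, 2 or 3 or fasted PP replicate 2 or 3. The 6 gluconeogenesis genes lower in PC became 3 without fasted PC replicate 3 or fasted PP replicate 2. The 9 amino acid catabolism genes lower in PC became 4 without fasted PC replicate 3 and 5 without fed PC replicate 2, fasted PC replicate 2 or fasted PP replicate 1 or 3, and the 2 higher in PC became 1 without fed PC replicate 1, 2 or 3, fed PP replicate 2, fasted PC replicate 1, 2 or 3 or fasted PP replicate 2 or 3. The 2 urea cycle genes lower in PC became 1 without fasted PC replicate 2 or 3 or fasted PP replicate 1.

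Of 27 xenobiotic metabolism genes, 11 were higher and 1 lower in fasted PC (17 and 2 adjusted over the list alone). Cyp2c38 had 2.94 ± 0.35 and Cyp2b10 -1.68 ± 0.25 (camera adjusted p = 1.6e-11, and adjusted p = 0.060 with an estimated correlation). Of 14 genes of bile acid synthesis and transport, 4 were higher and 1 lower (6 and 2 adjusted over the list alone). Cyp27a1 had 1.65 ± 0.18, and Nr0b2, a repressor of bile acid synthesis, -1.39 ± 0.22 (camera adjusted p = 1.9e-05, and adjusted p = 0.082 with an estimated correlation). Of 16 acute phase genes, 5 were lower in PC (7 adjusted over the list alone), with Lcn2, lipocalin 2, at -2.36 ± 0.30 and Hpx at -1.47 ± 0.15 (camera adjusted p = 7.2e-08, and adjusted p = 0.026 with an estimated correlation). Of 13 mitochondrially encoded genes, 8 were lower in PC (12 adjusted over the list alone), with mt-Nd1 at -0.69 ± 0.11 (camera adjusted p = 9.2e-09, and adjusted p = 0.118 with an estimated correlation). The 5 acute phase genes lower in PC became 3 without fasted PC replicate 2 or 3. The 8 mitochondrially encoded genes lower in PC became 2 without fasted PC replicate 2 or fasted PP replicate 1, 3 without fasted PC replicate 3 or fasted PP replicate 2 and 5 without fed PC replicate 1. Of 16 autophagy genes, 2 were higher and 1 lower in fasted PC (3 and 2 adjusted over the list alone; camera adjusted p = 0.425), and of 12 insulin and FoxO1 targets, 1 was lower (1 adjusted over the list alone; camera adjusted p = 0.859). The 2 autophagy genes higher in PC became 0 without fasted PC replicate 2 or fasted PP replicate 2 and 1 without fasted PC replicate 3. Xenobiotic metabolism genes lower in PC went from 1 to 2 without fasted PC replicate 1 and 3 without fasted PC replicate 2. Autophagy genes lower in PC went from 1 to 0 without fed PC replicate 1 or 2, fasted PC replicate 2 or 3 or fasted PP replicate 1, 2 or 3 and 2 without fed PP replicate 1. Insulin and FoxO1 targets lower in PC went from 1 to 0 without fasted PC replicate 1, 2 or 3 or fasted PP replicate 1 or 3.

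Camera also called lists with few or no called members in fasted mice. Of 25 cholesterol synthesis genes, 2 were higher in PC (3 adjusted over the list alone; camera adjusted p = 4.5e-05, and adjusted p = 0.552 with an estimated correlation), and of 19 genes of fatty acid oxidation and ketogenesis, 2 were higher (3 adjusted over the list alone; camera adjusted p = 0.00052, and adjusted p = 0.552 with an estimated correlation). Of 74 nuclear genes of oxidative phosphorylation, 3 were lower (1 adjusted over the list alone; camera adjusted p = 1.9e-05, and adjusted p = 0.666 with an estimated correlation; camera adjusted p = 0.0545 without fasted PP replicate 1). Of 18 cell cycle genes, 1 was lower (1 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.281 with an estimated correlation; camera adjusted p = 0.119 without fasted PC replicate 1). None of 20 PPARalpha targets was called (0 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.663 with an estimated correlation; camera adjusted p = 0.334 without fasted PC replicate 3 and 0.213 without fasted PP replicate 1). For the cytosolic ribosomal proteins list, zone in fasted mice, none of 81 genes was called (0 adjusted over the list alone), at a median of 0.09 (camera adjusted p = 0.048, and adjusted p = 0.852 with an estimated correlation). That camera call ended without fed PP replicate 2 (adjusted p = 0.052), fasted PC replicate 1 (0.082) or 2 (0.140), or fasted PP replicate 2 (0.800) or 3 (0.742). The 2 cholesterol synthesis genes higher in PC became 0 without fed PP replicate 2, fasted PC replicate 2 or 3 or fasted PP replicate 1 or 3 and 1 without fed PC replicate 1 or 2. The 2 genes of fatty acid oxidation and ketogenesis higher in PC became 0 without fasted PP replicate 1 or 3 and 1 without fed PC replicate 1, 2 or 3, fed PP replicate 2 or fasted PC replicate 1, 2 or 3. The 3 nuclear genes of oxidative phosphorylation lower in PC became 0 without fasted PC replicate 2 or 3, 1 without fed PC replicate 1, 2 or 3 or fasted PP replicate 1 and 5 without fed PP replicate 3. Cell cycle genes lower in PC went from 1 to 0 without fed PC replicate 2 or 3, fed PP replicate 2, fasted PC replicate 1, 2 or 3 or fasted PP replicate 2 or 3. PPARalpha targets higher in PC went from 0 to 1 without fed PP replicate 3 or fasted PC replicate 1 and 2 without fed PP replicate 1. Cytosolic ribosomal protein genes higher in PC went from 0 to 1 without fasted PC replicate 1.

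edgeR called 774 genes between the zones of fasted mice, 405 higher and 369 lower in PC. The larger side turned under upper-quartile scaling (318 higher and 440 lower), and without fasted PC replicate 1 (484 and 519), fasted PP replicate 1 (256 and 266) or fasted PP replicate 2 (287 and 300). A fit to only these 2 groups called 376, and the count was 387 without fasted PC replicate 2, 489 without fasted PC replicate 3 and 492 without fasted PP replicate 3. It was 1003 without fasted PC replicate 1.

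The zone differences of fed and fasted mice, which share no library, were alike across genes. 198 genes were higher and 192 lower in PC in both states, where independent calls would share 9.1 in each direction. The 1 gene called in opposite directions, named after its values were seen, was Cabyr, at -1.73 in fed and 2.65 in fasted mice. Over 8352 genes with a mean of at least 5 CPM, Pearson's r between the log2 fold changes was 0.836 and Spearman's rho 0.581, across genes, which are not independent replicates.

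In PC hepatocytes, Fasn and Srebf1 of fat synthesis fell with fasting, and Pck1 of gluconeogenesis rose. Fasn, fatty acid synthase, stood at 1816 ± 314 CPM in fed and 52.1 ± 11.01 CPM in fasted PC (SD, n = 3 each), a log2 fold change of -5.12 ± 0.51 (edgeR adjusted p = 0.00018). Pck1 rose from 127.9 ± 114 to 4524 ± 145 CPM, a log2 fold change of 5.14 ± 0.73 (edgeR adjusted p = 0.0012). Angptl4, an inhibitor of lipoprotein lipase, rose by 2.99 ± 0.32 (edgeR adjusted p = 0.00019). Pklr, the liver pyruvate kinase, fell by 2.85 on the log2 scale.

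The 5 genes that rose most in PC were Ppp1r3g, a glycogen-targeting phosphatase subunit (7.32 ± 2.07), Mt2, a metallothionein (5.53 ± 0.68), Pck1, Gadd45g (4.10 ± 0.64) and Cdkn1a, a cyclin-dependent kinase inhibitor (3.98 ± 0.74). The 5 that fell most were Pnpla3, a lipid droplet protein (-6.29 ± 1.05), Slc34a2, a phosphate transporter (-5.30 ± 0.97), Chrna4, an acetylcholine receptor subunit (-5.17 ± 1.18), Fasn and Elovl6, a fatty acid elongase (-5.09 ± 0.59). Fasn spans chromosome 11 from 120805846 to 120824547 and Pck1 chromosome 2 from 173153048 to 173159273. Ppp1r3g stood at 0.081 ± 0.141 CPM in fed PC, so the size of its fold is uncertain. Its call (edgeR adjusted p = 0.033) ended without fed PC replicate 1, 2 or 3 (0.106, 0.117 and 0.115), without fed PP replicate 1 (0.051) or 2 (0.052) and without fasted PC replicate 2 (0.091).

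Of 18 fatty acid synthesis genes, 11 fell and 0 rose in PC (12 and 1 adjusted over the list alone), with a median log2 fold change of -2.11 (camera adjusted p = 2.7e-10, and adjusted p = 0.344 with an estimated correlation). Srebf1, the transcription factor of lipid synthesis, fell by 2.98. Scd1, stearoyl-CoA desaturase, had -0.70 ± 0.77 (edgeR adjusted p = 0.56). Of 25 cholesterol synthesis genes, 13 fell and 0 rose (18 adjusted over the list alone), with Sc5d at -1.61 ± 0.21 and Insig1 at -1.55 ± 0.18 (camera adjusted p = 1.2e-08, and adjusted p = 0.412 with an estimated correlation). Of 13 genes of glycolysis and fructolysis, 6 fell and 0 rose (6 adjusted over the list alone), with Tkfc at -2.36 ± 0.21 (camera adjusted p = 7.7e-06, and adjusted p = 0.344 with an estimated correlation). Fatty acid synthesis genes that rose went from 0 to 1 without fasted PC replicate 1 or fasted PP replicate 1 or 2.

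Of 12 gluconeogenesis genes, 6 rose and 1 fell in PC (7 and 2 adjusted over the list alone). Got1, aspartate aminotransferase, rose by 1.85 ± 0.17 and G6pc, glucose-6-phosphatase, by 1.21 ± 0.25 (camera adjusted p = 0.0024, and adjusted p = 0.213 with an estimated correlation). Of 20 PPARalpha targets, 7 rose and 0 fell (8 adjusted over the list alone), among them Cpt1a, which carries fatty acids towards oxidation, at 1.19 ± 0.14 (camera adjusted p = 1.4e-05, and adjusted p = 0.377 with an estimated correlation). Of 19 genes of fatty acid oxidation and ketogenesis, 4 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 0.00064, and adjusted p = 0.729 with an estimated correlation). Fgf21, a fasting hormone, had -0.89 ± 0.84 (edgeR adjusted p = 0.49) and Pdk4, pyruvate dehydrogenase kinase, 2.27 ± 0.72 (0.052), and neither was called. Pdk4 was called at 2.73 without fasted PC replicate 1 and at 2.25 without fasted PP replicate 1. The 6 gluconeogenesis genes that rose became 3 without fed PC replicate 3. The 7 PPARalpha targets that rose became 3 without fed PC replicate 2 or fasted PC replicate 3 and 4 without fed PC replicate 3. The 4 genes of fatty acid oxidation and ketogenesis that rose became 1 without fed PC replicate 2 or 3 or fasted PC replicate 3, 2 without fasted PC replicate 1 or fasted PP replicate 1 or 2 and 10 without fed PP replicate 1. Gluconeogenesis genes that fell went from 1 to 0 without fed PC replicate 2 or 3 or fasted PC replicate 1, 2 or 3.

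Of 12 insulin and FoxO1 targets, 6 rose and 2 fell in PC (6 and 2 adjusted over the list alone). Irs2, the insulin receptor substrate, rose by 3.43 ± 0.40 and Igfbp1 by 3.21 ± 0.57 (camera adjusted p = 0.030, and adjusted p = 0.344 with an estimated correlation; camera adjusted p = 0.053 without fed PC replicate 2). Of 16 autophagy genes, 7 rose and 0 fell (7 adjusted over the list alone), with Map1lc3b, an autophagosome protein, at 1.01 ± 0.10 (camera adjusted p = 0.0015, and adjusted p = 0.344 with an estimated correlation). Of 18 genes of the unfolded protein response, 12 fell and 3 rose (12 and 3 adjusted over the list alone; camera adjusted p = 4.7e-05, and adjusted p = 0.377 with an estimated correlation). Those that fell include the endoplasmic reticulum chaperone genes Calr (-0.89 ± 0.13) and Pdia6 (-0.98 ± 0.14), and those that rose include Herpud1, of protein degradation at the endoplasmic reticulum (1.08 ± 0.20), and Chac1 (2.95 ± 0.60). The 7 autophagy genes that rose became 4 without fed PC replicate 3. The 12 genes of the unfolded protein response that fell became 7 without fed PC replicate 1 or 2 or fasted PC replicate 2 or 3. Of 27 genes of amino acid catabolism, 6 rose and 0 fell in PC (6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.102) but called it without fasted PC replicate 2 (0.0065). Of 74 nuclear genes of oxidative phosphorylation, 2 rose (0 adjusted over the list alone; camera adjusted p = 0.081, and 0.027 without fed PC replicate 3). Of 14 genes of bile acid synthesis and transport, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.739). The 2 nuclear genes of oxidative phosphorylation that rose became 0 without fasted PC replicate 2, 1 without fed PC replicate 1, 2 or 3 and 4 without fasted PP replicate 1. Amino acid catabolism genes that fell went from 0 to 1 without fed PP replicate 3, fasted PC replicate 1 or fasted PP replicate 3. Genes of bile acid synthesis and transport that rose went from 1 to 2 without fasted PC replicate 1 or fasted PP replicate 3.

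edgeR called 2583 genes for fasting in PC, 1345 higher and 1238 lower after fasting. Leaving out fed PC replicate 2 gave 1669 and leaving out fed PC replicate 3 gave 1593. Without fasted PC replicate 1 the count was 2487. Which side was larger depended on the setting: it turned under upper-quartile scaling (1140 higher and 1451 lower), with no filter on low counts (999 higher and 1179 lower) and in a fit to only these 2 groups (1342 higher and 1356 lower). It also turned without fed PC replicate 2 (803 and 866), fed PC replicate 3 (788 and 805), fed PP replicate 1 (1271 and 1314), fed PP replicate 2 (1153 and 1194), fasted PC replicate 1 (1185 and 1302), fasted PC replicate 3 (1018 and 1030), fasted PP replicate 1 (1281 and 1301), fasted PP replicate 2 (1224 and 1278) or fasted PP replicate 3 (1284 and 1331).

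In PP hepatocytes, Fasn, Elovl6 and Srebf1 of lipid synthesis fell with fasting, and Pck1 and Got1 of gluconeogenesis rose. Fasn fell from 1818 ± 878 to 94.9 ± 55.0 CPM, a log2 fold change of -4.26 ± 0.49 (edgeR adjusted p = 0.00044). Pck1 rose from 798 ± 470 to 8340 ± 1963 CPM, a log2 fold change of 3.39 ± 0.67 (edgeR adjusted p = 0.0078). Angptl4 rose by 3.23 ± 0.32 (edgeR adjusted p = 0.00018). Srebf1 fell by 2.63 and Pklr by 2.03 on the log2 scale.

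The 5 genes that rose most in PP were Mt2 (5.35 ± 0.67), Cdkn1a (3.61 ± 0.70), Igfbp1 (3.58 ± 0.58), Mt1, a metallothionein (3.54 ± 0.57), and Hdc, histidine decarboxylase (3.40 ± 0.47). The 5 that fell most were Chrna4 (-6.20 ± 1.24), Pnpla3 (-5.67 ± 0.96), Slc34a2 (-5.10 ± 0.88), Elovl6 (-4.74 ± 0.58) and Fasn. Mt2 spans chromosome 8 from 94172664 to 94173568 and Mt1 chromosome 8 from 94179082 to 94180327. These neighbours are similar in sequence, and their values are uncertain.

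Of 18 fatty acid synthesis genes, 12 fell and 1 rose in PP (14 and 1 adjusted over the list alone), with a median of -1.94 (camera adjusted p = 1.5e-09, and adjusted p = 0.372 with an estimated correlation). The gene that rose was Pcx, pyruvate carboxylase, which also serves gluconeogenesis (0.93 ± 0.25), and its call ended without fed PP replicate 2 (edgeR adjusted p = 0.087), fed PP replicate 3 (0.089) or fasted PP replicate 2 (0.090). Scd1 had -0.85 ± 0.77 (edgeR adjusted p = 0.50). Of 25 cholesterol synthesis genes, 14 fell and 0 rose (14 adjusted over the list alone) (camera adjusted p = 1.5e-09, and adjusted p = 0.450 with an estimated correlation). Of 18 genes of the unfolded protein response, 12 fell and 2 rose (12 and 3 adjusted over the list alone), with Hyou1 at -2.08 ± 0.28 and Herpud1 at 1.29 ± 0.20 (camera adjusted p = 2.5e-06, and adjusted p = 0.372 with an estimated correlation). Of 13 genes of glycolysis and fructolysis, 5 fell and 0 rose (6 adjusted over the list alone), with Tkfc at -1.08 ± 0.20 (camera adjusted p = 0.009, and adjusted p = 0.634 with an estimated correlation). The 14 cholesterol synthesis genes that fell became 9 without fed PP replicate 3. The 2 genes of the unfolded protein response that rose became 1 without fed PP replicate 3. The 5 glycolysis and fructolysis genes that fell became 3 without fed PP replicate 2 or 3 or fasted PP replicate 1 or 2.

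Of 12 gluconeogenesis genes, 6 rose and 0 fell in PP (8 adjusted over the list alone), with Got1 at 1.77 ± 0.17 (camera adjusted p = 0.00011, and adjusted p = 0.056 with an estimated correlation). G6pc had 0.94 ± 0.25 (edgeR adjusted p = 0.023), a call that ended without fed PP replicate 1 (0.074), fed PP replicate 3 (0.093) or fasted PP replicate 2 (0.081). Of 20 PPARalpha targets, 5 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.450 with an estimated correlation), among them Cpt1a at 1.12 ± 0.14. Cpt1a was also the 1 called gene of 19 in fatty acid oxidation and ketogenesis (1 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.677 with an estimated correlation; camera adjusted p = 0.086 without fed PP replicate 3). Fgf21 had -1.24 ± 0.82 (edgeR adjusted p = 0.341). Pdk4 had 3.40 ± 0.78 (edgeR adjusted p = 0.016; 0.060 without fed PP replicate 1 and 0.066 without fed PP replicate 2). Of 12 insulin and FoxO1 targets, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Irs2 at 2.83 ± 0.39 and Klf15 at 1.25 ± 0.20 (camera adjusted p = 0.0020, and adjusted p = 0.094 with an estimated correlation). Of 27 genes of amino acid catabolism, 6 rose and 0 fell (7 adjusted over the list alone), with Tdo2, which degrades tryptophan, at 1.06 ± 0.16 (camera adjusted p = 0.00029, and adjusted p = 0.372 with an estimated correlation). Of 16 autophagy genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Bnip3 at 0.73 ± 0.13 and Sqstm1, an autophagy receptor, at -0.59 ± 0.12 (camera adjusted p = 0.030, and adjusted p = 0.520 with an estimated correlation). The autophagy list was not called without fed PP replicate 3 (camera adjusted p = 0.094) or fasted PP replicate 1 (0.060). The 6 gluconeogenesis genes that rose became 3 without fed PP replicate 1 or 2. The 5 PPARalpha targets that rose became 8 without fasted PP replicate 1 and 10 without fed PP replicate 1. The 6 amino acid catabolism genes that rose became 10 without fasted PC replicate 1. Of 14 genes of bile acid synthesis and transport, 1 rose and 1 fell in PP (1 and 1 adjusted over the list alone; camera adjusted p = 0.886). Genes of fatty acid oxidation and ketogenesis that rose went from 1 to 3 without fasted PP replicate 1 and 10 without fed PP replicate 1, and those that fell from 0 to 1 without fed PP replicate 3. Genes of bile acid synthesis and transport that rose went from 1 to 0 without fed PP replicate 2 or 3 or fasted PP replicate 2, and those that fell from 1 to 0 without fed PP replicate 2 or 3 or fasted PP replicate 1 or 3.

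Some zone markers were called for fasting. Of 24 pericentral markers, 4 fell and 0 rose in PP (4 adjusted over the list alone), with Cyp1a2 at -1.97 ± 0.39 and Cyp2c50, which is uncertain for its close paralogs, at -1.02 ± 0.21 (camera adjusted p = 0.0012, and adjusted p = 0.634 with an estimated correlation). Of 24 periportal markers, 5 rose and 1 fell in PP (5 and 1 adjusted over the list alone), with Arg1, arginase, at 0.85 ± 0.19 and Cdh1 at -1.32 ± 0.26 (camera adjusted p = 0.017, and adjusted p = 0.680 with an estimated correlation; camera adjusted p = 0.106 without fed PP replicate 1). In PC, 1 pericentral marker fell and 0 rose (1 adjusted over the list alone; camera adjusted p = 0.254, and 0.0052 without fasted PC replicate 2), while 5 periportal markers rose and 0 fell (5 adjusted over the list alone), with Mfsd2a, a lysophospholipid transporter, at 1.55 ± 0.30 (camera adjusted p = 0.018, and adjusted p = 0.729 with an estimated correlation). That list was not called in PC without fasted PC replicate 1 (camera adjusted p = 0.632). The 5 periportal markers that rose in PP became 2 without fed PP replicate 1 or 2, 3 without fasted PP replicate 1 or 3 and 9 without fasted PC replicate 1, and the 5 that rose in PC became 3 without fed PC replicate 3 and 9 without fasted PC replicate 2. Pericentral markers that fell in PC went from 1 to 0 without fed PC replicate 3, 2 without fed PP replicate 3 and 3 without fasted PC replicate 2, and those that rose in PC from 0 to 2 without fasted PC replicate 1. Periportal markers that fell in PC went from 0 to 1 without fasted PC replicate 1.

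edgeR called 2163 genes for fasting in PP, 1014 higher and 1149 lower after fasting. Leaving out fed PP replicate 2 gave 1405. Without fasted PC replicate 1 the count was 2415. The larger side turned in a fit to only these 2 groups (793 higher and 780 lower), and without fasted PP replicate 1 (797 and 737).

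**Figure D3:**
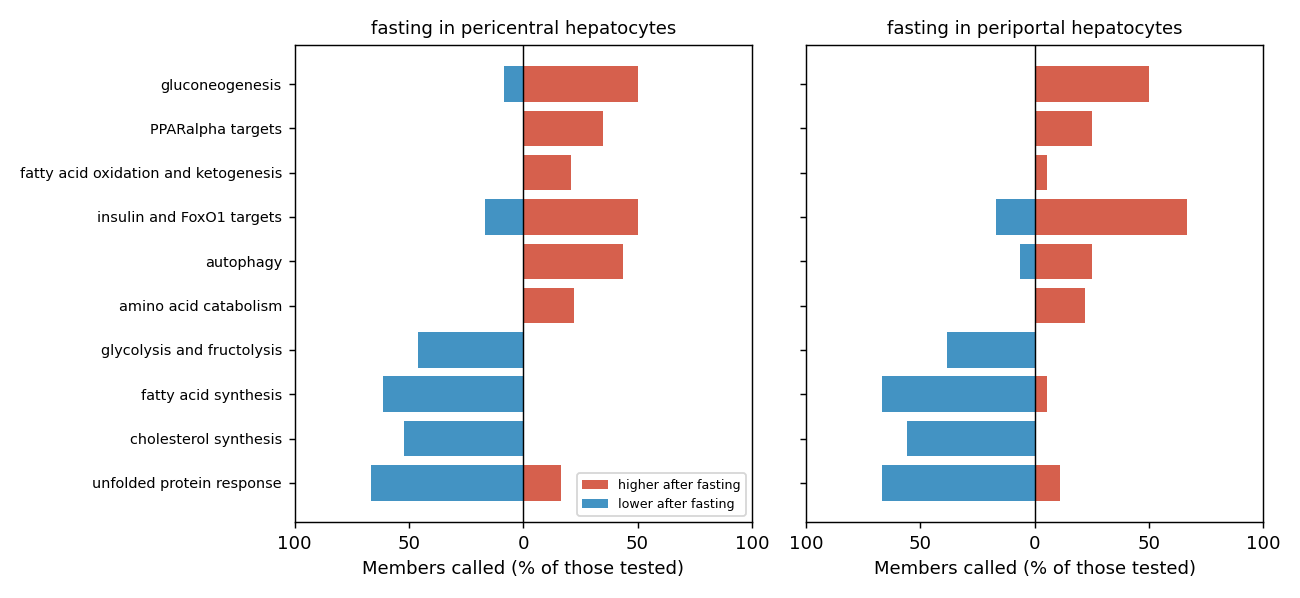
Members of 10 gene lists called by edgeR for fasting, as a percent of those tested (x axis), in PC (left) and PP (right), with members higher after fasting to the right of 0 and members lower to the left. Of 18 fatty acid synthesis genes, 11 fell in PC and 12 in PP.

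The fasting responses of the zones, which share no library, were alike across genes. 764 genes rose and 780 fell in both zones, where independent calls would share 112.8 and 117.7. The 1 gene called in opposite directions, named after its values were seen, was Abcc3, a bile salt exporter, at 0.48 in PC and -0.51 in PP. Over the 8352 genes, Pearson's r between the log2 fold changes was 0.864 and Spearman's rho 0.817, across genes.

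**Figure D4:**
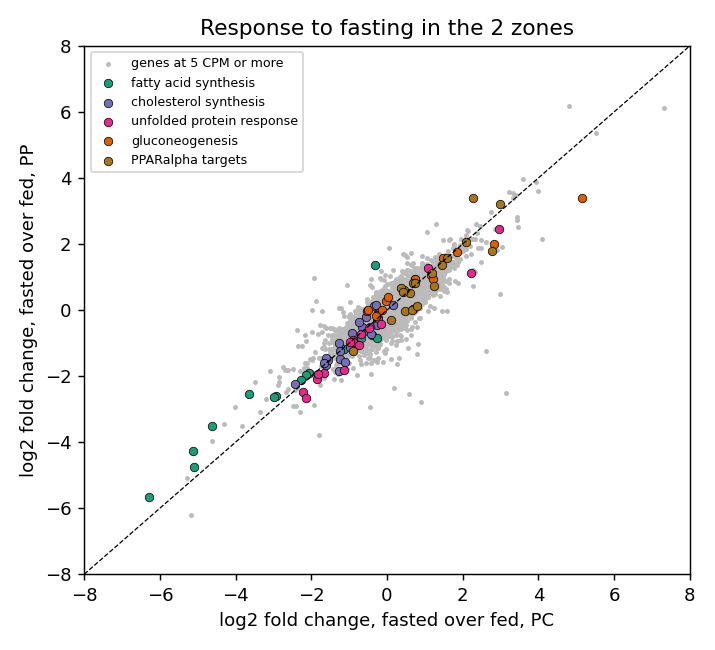
Log2 fold change of fasted over fed in PC (x axis) against PP (y axis), with grey points for genes at 5 CPM or more on average and coloured points for the members of 5 lists. The dashed line marks equal change, and Pearson's r over the grey points is 0.864.

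Whether the response to fasting differed between the zones was tested by the interaction. No gene passed in edgeR (0 calls, with 465 genes at an unadjusted p under 0.05). limma-voom called 0 genes and the Wald test of DESeq2 called 11. The response of Pck1 differed by 1.76 ± 0.87 between PC and PP, with an unadjusted edgeR p of 0.072 and an adjusted p of 0.997. Glul had 0.75 ± 1.15, Oat 0.29 ± 0.75 and Scd1 0.16 ± 1.08, differences within their errors. Without fasted PC replicate 1, 2 genes were called, Slc1a2 at 2.68 and Spry4 at -3.73, and with no filter on low counts the 1 call was Cabyr at 4.33. Spry4 and Cabyr were named after their values were seen. Adjusted over the list alone, 2 autophagy genes passed with a higher response in PC, and 1 gene of glycolysis and fructolysis and 1 acute phase gene with a lower one. Camera called 7 of 28 lists for the interaction, each with an adjusted p of 0.794 or more with an estimated correlation. With the replicate number as a block it also called fatty acid synthesis (camera adjusted p = 0.0224 with the block and 0.208 without it). That list was also called without fed PC replicate 1 (camera adjusted p = 0.013), fed PP replicate 2 (0.010), fed PP replicate 3 (0.042) or fasted PP replicate 1 (0.012).

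Markers of other liver cells were rarely called. Of 6 cholangiocyte markers, 1 was lower in fed PC than PP (Sox9, -1.80 ± 0.30) and 2 in fasted PC (Sox9 at -1.70 ± 0.32, Spp1 at -1.51 ± 0.24), and 3 and 6 adjusted over the list alone (camera adjusted p = 0.0010 and 1.9e-05, and adjusted p = 0.051 and 0.013 with an estimated correlation). With fasting in PC, 1 cholangiocyte marker fell (1 adjusted over the list alone), Spp1 at -0.89 ± 0.23, a call that ended without fed PC replicate 2 (edgeR adjusted p = 0.0739), fasted PC replicate 1 (0.0551) or fasted PC replicate 2 (0.0646). Of 11 endothelial markers, 1 fell with fasting in PC (Fcgr2b, -2.15 ± 0.44) (1 adjusted over the list alone), and 0 were called between the zones. None of 8 Kupffer cell and macrophage markers, 4 stellate cell markers, 5 erythroid markers and 1 lymphocyte and neutrophil marker was called by edgeR in any of the 5 comparisons with all libraries. Adjusted over the list alone, 1 stellate cell marker was higher in fed PC and the lymphocyte and neutrophil marker was higher after fasting in PC, and 0 of the others passed. The 2 cholangiocyte markers lower in PC became 4 without fasted PC replicate 1. These lists were not shown to be level. Erythroid markers had a median log2 fold change of 3.60 with fasting in PC and 3.48 in PP, and of 1.48 and 1.45 between the zones of fed and fasted mice (camera adjusted p = 0.706, 0.775, 0.708 and 0.575). Hba-a1, an alpha globin whose close copy makes its values uncertain, stood at 102.3 CPM in fasted PC replicate 2 and 32.46 CPM in fasted PP replicate 3, and at 6.96 CPM or less in the other 10 libraries. Stellate cell markers had a median of -1.09 with fasting in PC (camera adjusted p = 0.490). Leaving out 1 library gave a call between the zones of fasted mice to Alas2 at 1.47 without fasted PC replicate 1 (edgeR adjusted p = 0.017), an erythroid marker, and to Fcgr2b at -1.77 without fasted PP replicate 3 (edgeR adjusted p = 0.043). With fasting in PC it gave calls to Reln at -2.05 without fasted PC replicate 2 (edgeR adjusted p = 0.031), a stellate cell marker, and to Cd3d at 1.52 without fasted PC replicate 2 (edgeR adjusted p = 0.044), the lymphocyte marker. With fasting in PP it gave calls to Fcgr2b at -1.56 without fasted PP replicate 2 (edgeR adjusted p = 0.0082) and Kdr at -1.82 without fasted PP replicate 2 (edgeR adjusted p = 0.047), an endothelial marker. The 1 cholangiocyte marker lower in fed PC became 3 without fasted PC replicate 1 and 2 without fasted PC replicate 3 or fasted PP replicate 2. The 1 that fell with fasting in PC became 0 without fed PC replicate 2 or fasted PC replicate 2, 2 without fasted PC replicate 3, and another gene, Pkhd1 at -1.19 without fasted PC replicate 1 (edgeR adjusted p = 0.019). As lists, camera called Kupffer cell markers between the zones of fasted mice without fasted PC replicate 3 (adjusted p = 0.024, and 0.209 with all libraries). It called endothelial markers between the zones of fasted mice without fasted PP replicate 3 (0.012, and 0.264 with all libraries) and for fasting in PP without fasted PP replicate 2 (0.034, and 0.886 with all libraries). It called stellate cell markers between the zones of fed mice without fed PC replicate 2 (0.021), fed PC replicate 3 (0.016) or fed PP replicate 1 (0.035), against 0.130 with all libraries. The medians with all libraries were -0.60 for Kupffer cell and -1.12 for endothelial markers in fasted mice and 1.30 for stellate cell markers in fed mice, PC over PP.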

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

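The tests of fasted PC replicate 1 and of other splits of the libraries, and the gene list tests with libraries left out, were chosen only after the results were seen.

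Camera called 7 lists for a difference between the zones in the response to fasting, given here as the median log2 difference, PC minus PP. Pericentral markers had 0.57 (camera adjusted p = 0.0011) and xenobiotic metabolism 0.28 (0.039). Cytosolic ribosomal proteins had 0.17 (camera adjusted p = 1.0e-05). Cell cycle genes had -0.57 (camera adjusted p = 0.0011), mitochondrially encoded genes -0.27 (0.00040), glycolysis and fructolysis -0.17 (0.00040) and amino acid catabolism -0.13 (0.010). With an estimated correlation the adjusted p of each was between 0.794 and 0.898, and edgeR called 0 single genes (465 at an unadjusted p under 0.05, 11 by the Wald test of DESeq2 and 0 by limma-voom). With the replicate number as a block, camera called the same 7 and the fatty acid synthesis list, zone by fasting interaction. That list had a median of -0.19 and an adjusted p of 0.0224 with the block, 0.208 without it and 0.898 with an estimated correlation, in a range of 0.0101 to 0.970 over its alternatives. It was also called without fed PC replicate 1 (0.013), fed PP replicate 2 (0.010), fed PP replicate 3 (0.042) or fasted PP replicate 1 (0.012). Of the 21 lists not called with all libraries, 14 were called when some 1 library was left out. Leaving out 1 library ended the camera call of 5 of the 7: amino acid catabolism (0.191 without fasted PC replicate 2, 0.173 without fasted PP replicate 1), cell cycle (0.271 without fasted PC replicate 1), ribosomal proteins (0.085 without fasted PP replicate 3), pericentral markers (0.191 without fasted PC replicate 2, 0.173 without fasted PP replicate 3) and xenobiotic metabolism. The last ended without fed PC replicate 1 (0.079) or 3 (0.062), fed PP replicate 1 (0.143) or 3 (0.114), fasted PC replicate 2 (0.386), or fasted PP replicate 1 (0.138) or 3 (0.178).

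In fasted PC replicate 1, Glul stood at 172.0 CPM against 3639 and 2353 in the other fasted PC libraries, Oat at 452.4 against 2309 and 1971, and Hal at 578.9 against 69.9 and 108.6. The share of the way from the other fasted PC libraries to fasted PP was measured for 41 zone markers called in fed mice without this library. It had a median of 0.556 (quartiles 0.341 and 0.795) for 21 pericentral markers and 0.208 (0.0774 and 0.413) for 20 periportal markers, a difference of 0.348 (permutation p = 0.0001). This argues against a plain admixture of periportal cells, since that would move both lists by 1 share. The median over both lists was 0.402, against 0.981 to 1.02 in the fasted PP libraries, which argues against a label swapped with a PP library. Pericentral markers most restricted to PC in fed mice had moved farthest (Spearman's rho across genes = -0.678), so a lower share of cells from next to the central vein is a candidate explanation. A loss of the same transcripts in that mouse would look alike and was not tested. This marker choice replaced, after its values were seen, one with all libraries, where Glul, Hal and Gls2 did not pass. That left 36 markers, a difference of 0.3675, a joint median of 0.336 and a rho of -0.713. An earlier label test, 12 of those 36 nearer to PP, had not decided it.

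Other splits of the libraries of each comparison were counted. For 3 against 3 libraries, 10 splits are too few for a share under 0.05, and only the real split, 1 of 10, gave as many calls. Real counts were 570 and 774 between zones in fed and fasted mice, against at most 1 and 31 in other splits. They were 2583 and 2163 for fasting in PC and PP, against 0. Other splits mix real groups, which widens spread, so their low counts do not address chance. For the interaction the real count was 0, which every split reaches (100 of 100), so this count says nothing about chance. The highest of those splits gave 1567 genes, with the zones exchanged in fasted mice, since that contrast adds the zone differences of both states.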

How the results depend on the processing

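The lists with libraries left out were tested only after the results were seen; the other alternatives were planned. Counts of genes past the threshold stayed within 1.5 times under both other scalings, limma-voom, a mean CPM of at least 1, removal of the 20 most abundant genes and the replicate block. The Wald test of DESeq2 moved the zone count in fed mice to 929 and the interaction to 11, a fit to only the groups compared moved the zone count in fasted mice to 376, and no filter on low counts gave 1 interaction call. Leaving out 1 library gave 292 to 700 genes for the zone in fed mice, 387 to 1003 for the zone in fasted mice, 1593 to 2615 for fasting in PC, 1405 to 2415 for fasting in PP and 0 to 2 for the interaction, with fewer libraries as part of each fit. Pairing by replicate number stayed open. Same-numbered libraries correlated in their deviations from group means at 0.024 to 0.269 (zone, fed), others at -0.213 to 0.068. Ranges were -0.115 to 0.193 and -0.27 to 0.217 (zone, fasted), and -0.003 to 0.098 and -0.099 to 0.057 (fasting). The replicate block gave 626, 796, 2696, 2224 and 0 genes.

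Of the values of named genes under the alternatives, 3409 kept their side of the threshold, 25 gained and 284 lost the call, and 0 called values changed sign. Under each left-out library, 25 of 36 named calls were kept for the zone in fed mice, 34 of 50 in fasted mice, 48 of 61 for fasting in PC and 44 of 61 in PP. Of list tests, 2071 kept their side, 52 gained and 113 lost the call, 52 of these with an estimated correlation and 24 with fry. In 4 tests of the zone by fasting interaction the direction turned. The cholesterol synthesis list, zone by fasting interaction, turned without fed PP replicate 1 (camera adjusted p = 0.0375) and fasted PP replicate 2 (0.0386), in a range of 0.0121 to 0.900 over the left-out libraries. The endothelial cell markers list, zone by fasting interaction, turned without fasted PP replicate 2 (0.0386; range to 0.944), and the periportal markers list, zone by fasting interaction, without fasted PC replicate 1 (0.00043; range to 0.782). The cause was not tested. Genes changed less than 2-fold are at the limit of this design: 9.1% to 23.9% of those changed 1.5-fold were recovered between 2 groups of simulated data.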

Other observations

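The test of Scd1 with the replicate block was chosen only after the result was seen, and its rule was changed after its values were seen.

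Per1 and Per2 of the circadian clock were called for fasting in both zones, in mice killed at the same time of day. Of 17 clock genes, 5 rose and 3 fell in PC (7 and 3 adjusted over the list alone) and 6 rose and 2 fell in PP (7 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.452 and 0.312). Camera tests for a shift of a list in 1 direction, so its result does not speak against a response with members moving both ways. Per1 rose by 1.92 ± 0.40 in PC and 1.97 ± 0.40 in PP, and Per2 fell by 2.02 and 1.48 on the log2 scale. Of 18 cell cycle genes, 1 rose and 2 fell in PC (0 and 2 adjusted over the list alone) and 1 fell in PP (1 adjusted over the list alone), with Ccnd1, cyclin D1, at -2.42 ± 0.50 and -2.92 ± 0.50 (camera adjusted p = 0.254 and 0.676). Of 12 glycogen genes, 3 rose and 4 fell in PC (3 and 5 adjusted over the list alone) and 3 rose and 2 fell in PP (3 and 3 adjusted over the list alone), with Pygl, glycogen phosphorylase, at -1.08 ± 0.19 in PC (camera adjusted p = 0.361 and 0.730). The 5 clock genes that rose in PC became 2 without fed PC replicate 2 or 3 and 3 without fasted PC replicate 2, and the 6 that rose in PP became 1 without fed PP replicate 2 or 3 or fasted PP replicate 1, 2 without fasted PP replicate 3 and 3 without fed PC replicate 2, fasted PC replicate 2 or fasted PP replicate 2. The 2 cell cycle genes that fell in PC became 4 without fasted PC replicate 3. The 3 glycogen genes that rose in PC became 0 without fed PC replicate 2 or 3 or fasted PC replicate 2 and 1 without fed PP replicate 1 or 2 or fasted PC replicate 3, and the 3 that rose in PP became 0 without fed PC replicate 2 or 3 or fed PP replicate 1 or 2 and 1 without fed PC replicate 1, fasted PC replicate 2 or fasted PP replicate 1 or 2. The 2 that fell in PP became 0 without fed PP replicate 3 and 1 without fasted PP replicate 1 or 2. Camera called the cell cycle list in PC without fasted PC replicate 3 (adjusted p = 0.042). Cell cycle genes that rose in PC went from 1 to 0 without fed PC replicate 1, 2 or 3, fed PP replicate 1, 2 or 3, fasted PC replicate 2 or 3 or fasted PP replicate 1 or 2.

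Of 20 immediate-early and heat-shock genes, which respond to cell isolation, 1 rose and 1 fell in PC (1 and 1 adjusted over the list alone) and 2 rose and 2 fell in PP (2 and 2 adjusted over the list alone), and 0 were called between the zones with all libraries (0 adjusted over the list alone). Their median log2 difference between the zones, PC over PP, was -0.36 in fed and -0.42 in fasted mice (camera adjusted p = 0.329 and 0.271). Camera called the list in fed mice without fed PC replicate 1 (0.014) and in fasted mice without fasted PC replicate 2 (0.030) or fasted PP replicate 2 (0.0011), so a difference in the response to isolation between the zones was not excluded. Klf6 rose by 1.17 ± 0.26 and 1.53 ± 0.26, and Hspa8, a chaperone, fell by 1.05 and 1.27 on the log2 scale (camera adjusted p = 0.858 and 0.886). Of 27 xenobiotic metabolism genes, 4 rose and 2 fell in PC and 4 rose and 3 fell in PP (4 and 2, and 5 and 3, adjusted over the list alone), with Por, the reductase of cytochromes P450, at 1.31 ± 0.16 in each zone (camera adjusted p = 0.452 and 0.777). Of 81 cytosolic ribosomal protein genes, 7 rose and 2 fell in PC (0 and 1 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.729 with an estimated correlation), and 2 fell in PP (1 adjusted over the list alone; camera adjusted p = 0.068). Rpl7l1, a paralog of Rpl7, fell in both, by 0.77 and 0.79 on the log2 scale. Of 16 acute phase genes, 1 rose in PC and 3 rose in PP (1 and 3 adjusted over the list alone), with Lbp, which binds bacterial lipopolysaccharide, at 1.01 ± 0.15 and 0.96 ± 0.15 (camera adjusted p = 0.254 and 0.063). Of 8 urea cycle genes, 1 rose in PC and 2 rose in PP (1 and 3 adjusted over the list alone), with Arg1 at 0.83 ± 0.19 and 0.85 ± 0.19 (camera adjusted p = 0.570 and 0.225). The 2 immediate-early and heat-shock genes that rose in PP became 1 without fed PC replicate 1, 2 or 3, fed PP replicate 1, 2 or 3 or fasted PP replicate 1 or 3 and 4 without fasted PP replicate 2, and the 2 that fell in PP became 1 without fed PP replicate 1 or 2 or fasted PP replicate 1 or 2. The 2 xenobiotic metabolism genes that fell in PC became 1 without fed PC replicate 3 and 4 without fasted PC replicate 2, and the 3 that fell in PP became 1 without fed PP replicate 1, 2 or 3. The 7 cytosolic ribosomal protein genes that rose in PC became 0 without fed PC replicate 1, 2 or 3, fed PP replicate 2 or fasted PC replicate 1 or 2, 1 without fasted PC replicate 3, 4 without fasted PP replicate 2, 18 without fed PP replicate 3 and 24 without fasted PP replicate 1, and the 2 that fell in PC became 1 without fed PC replicate 1 or 3 or fasted PC replicate 2. The 2 that fell in PP became 1 without fed PP replicate 1, 2 or 3 or fasted PP replicate 1 or 2. The 2 urea cycle genes that rose in PP became 1 without fed PP replicate 1 or 2 or fasted PP replicate 1. Camera called the acute phase list in PP without fed PP replicate 1 (adjusted p = 0.027) or fed PP replicate 2 (0.028), and the ribosomal protein list in PP without fed PP replicate 1 (0.0029), fed PP replicate 2 (0.0095), fasted PP replicate 2 (0.0010) or fasted PP replicate 3 (0.0021). Immediate-early and heat-shock genes lower in PC of fed mice went from 0 to 1 without fasted PC replicate 1 or 2, and those higher in PC of fasted mice from 0 to 2 without fasted PC replicate 1. Those lower in PC of fasted mice went from 0 to 1 without fasted PC replicate 2 and 3 without fasted PP replicate 2, and those that rose in PC from 1 to 2 without fed PC replicate 1 or 3 or fasted PP replicate 2 and 3 without fasted PC replicate 3. Those that fell in PC went from 1 to 2 without fed PC replicate 2, fed PP replicate 1 or 3, fasted PC replicate 3 or fasted PP replicate 2. Acute phase genes that rose in PC went from 1 to 2 without fasted PC replicate 1 or 2. In PP, 0 of 74 nuclear genes of oxidative phosphorylation and 0 of 13 mitochondrially encoded genes were called (0 and 0 adjusted over the list alone; camera adjusted p = 0.051 and 0.063). Camera called the first list without fed PP replicate 1 (0.0063), fed PP replicate 2 (0.0075), fasted PP replicate 2 (0.0042) or fasted PP replicate 3 (0.0036), and the second without fed PP replicate 1 (0.037) or fasted PP replicate 3 (0.023). Members of the first list that rose in PP went from 0 to 2 without fasted PP replicate 2 or 3, and those of the second from 0 to 1 without fasted PC replicate 1 or fasted PP replicate 3.

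Scd1 did not pass the test while most fatty acid synthesis genes fell. It stood at 9305, 8665 and 13640 CPM in fed PC, 4787, 15520 and 13390 in fed PP, 1692, 8903 and 8927 in fasted PC and 1471, 7199 and 9982 in fasted PP. The hypothesis tested was that differences between replicate numbers hide a fall of Scd1. With the replicate number as a block, the log2 fold change was -1.13 ± 0.49 in PC (edgeR adjusted p = 0.142) and -1.02 ± 0.47 in PP (0.182), so the block did not uncover a fall. The first rule took this alone as evidence against the hypothesis. The rule that replaced it asks instead, for evidence against, that Scd1 lie more than 2 SE above the median of its list (-2.11 in PC and -1.94 in PP) in both zones, and it lay 2.001 SE above in PC and 1.93 SE in PP. The verdict hangs on the choice between these rules, and the hypothesis may be right or wrong. The numbers are not known to mark a shared mouse or day.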
